A study of Homo sapiens with 4 samples.

How the data were processed

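RNA was sequenced from 4 libraries of the human cell line K562. Samples were grouped by the titles and treatments in the labels, into 2 libraries transduced with a control hairpin (shControl) and 2 transduced with a hairpin against PHF8 (shPHF8). The authors deposited 1 table of transcript abundances in TPM (transcript abundance scaled to the same total in every library), with 1 TPM column per library, per the file headers. Per the submitters' processing notes, HISAT2 2.0.4 and StringTie 1.2.3 were used with the genome build hg19; the role of each tool, the gene annotation, the strandedness of the libraries and the choice of transcripts are not given in the sources used here. The labels give total RNA as the molecule and do not state whether polyadenylated RNA was selected.

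The table lists 32551 transcripts under 11213 gene names, and each TPM column sums to 1000000 over them. A further set of 4 deposited columns carries no unit and is described here only as signal; within each library it was an exact multiple of TPM, with TPM from 3.1552 to 3.1872 times as large, and it was not used for any result. Of 11219 gene identifiers, taken without their version, 11111 were found in GENCODE release 29. That release is on another build than the files, so it was used for gene types and current symbols and no coordinates are given. Of the 32329 transcripts found there, 99.7% were protein-coding, so nearly all TPM are shares of the protein-coding transcripts listed. TPM keep no record of the number of reads. The depth of each library is therefore unknown, no counting error can be given, and the precision of each value is known only from the spread between libraries. A TPM is also a share, so a rise of abundant transcripts lowers all others. Sums over transcripts depend on how reads shared by isoforms or by near-identical genes were divided.

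TPM were summed per gene name and analysed as log2(TPM + 1). Fold changes on this scale understate the change of genes with low TPM. The 10972 genes with a mean of at least 1 TPM over the 4 libraries were tested and 241 were not. The comparison of shPHF8 with shControl used limma 3.58.1 (linear model, empirical Bayes with a mean-variance trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Residual degrees of freedom were 2 and the prior added 2.16. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so no such test is reported. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

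Before the data were examined, 32 gene lists were fixed: PHF8 family and partners, BCR and ABL1 loci, other H3K9 demethylases, H3K9 and H4K20 methyltransferases, BCR-ABL1 and STAT5 responsive genes, JAK-STAT, PI3K and RAS signalling components, globins, haem biosynthesis and iron uptake, erythroid membrane and transcription factors, megakaryocyte markers, granulocyte and monocyte markers, lymphocyte markers, stromal and endothelial markers, stem and progenitor markers, G1/S genes, G2/M genes, CDK inhibitors and p53-pathway genes, BCL2 family, RNA polymerase I and rRNA processing, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, glycolysis and hypoxia-responsive genes, amino acid response and unfolded protein response, cholesterol biosynthesis, interferon-stimulated genes, antigen presentation, immediate early genes, NF-kB responsive genes, replication-dependent histones, MYC target genes, and cytoskeleton and adhesion genes. The lists were written from general knowledge and not from these libraries. The 30 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, and limma's fry was run beside it; fry asks whether a list's genes move one way on balance and does not compare the list with other genes. Members were also adjusted over the list alone, by Benjamini-Hochberg on the limma p of that list's members; this adjustment does not correct for the number of lists.

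The genes to be named were also fixed before the data were examined: PHF8, BCR and ABL1; the 5 genes with the smallest p in each direction if none was called over all genes; and per list the 4 members with the smallest p where the list passed camera, or otherwise 2. This gave 87 genes, some of which are not reported here. Members named beyond these, to complete a count of 5 or fewer, were chosen after their values were seen.

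The limma step was tested on simulated data for shPHF8 against shControl, with 10972 genes and 200 changed genes in each of 10 runs. It called 18.5% of genes changed by 1 on the log2 scale, 58.7% of those changed by 2 and 80.2% of those changed by 3, and 0.05% of unchanged genes. The median estimates were 1.01, 2 and 3.02. Camera, tested on simulated data for the same comparison and genes, called 0 of 300 unchanged lists and 30 of 30 lists shifted by 1. Genes were drawn independently in these simulations, so the effect of correlation between genes on camera was not tested. No shift smaller than 1 was tried. The percentages of changed genes that limma called also depend on how many genes were changed and by how much. Both were set in the simulation and are unknown in the libraries.

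The alternatives tried were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without mitochondrially encoded genes and the 20 most abundant genes, empirical Bayes without the trend and with robust estimation, the replicate number as a block, and leaving out each library. A threshold of 0.1 on the adjusted p and a fit on genes with 1 listed transcript were added after seeing the data.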

Results

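RNA sequencing was collected from K562, a line established from a patient with chronic myelogenous leukaemia that carries the BCR-ABL1 fusion gene. The cells had been transduced with lentivirus carrying either a control hairpin or a hairpin against PHF8, and selected with puromycin. PHF8 is a demethylase of histone H3 lysine 9 and histone H4 lysine 20. There were 2 shControl and 2 shPHF8 libraries. The labels do not settle whether the numbers 1 and 2 of the knockdown libraries mark replicates or different hairpins. They also do not state that the libraries came from separate cultures, so p-values of single genes measure only the spread between these samples. Camera at the preset correlation weighs a list's genes against the other genes. Its p-values therefore do not measure the spread between libraries. Abundances were in TPM, so the number of reads behind each value is unknown. The 2 control libraries differed by more than 2-fold, on the log2(TPM + 1) scale, in 5.93% of the 10972 genes tested, the 2 knockdown libraries in 5.48%, and a control and a knockdown library in 8.38% to 9.93%. Values below are mean TPM ± SD over 2 libraries, and log2 fold changes are shPHF8 minus shControl on the log2(TPM + 1) scale with their standard error (SE).

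PHF8 fell in the knockdown libraries, and the summed transcripts of BCR and ABL1 showed no difference beyond the spread between libraries. PHF8 (ENSG00000172943) was at 25.9 and 22.5 TPM in the control libraries and at 6.06 and 6.42 TPM in the knockdown libraries, with means of 24.2 ± 2.38 and 6.24 ± 0.256 TPM (SD, n = 2). It thus stood at 25.8% of the control level. Its log2 fold change was -1.80 ± 0.16 (SE), with a 95% confidence interval from -2.23 to -1.36. It passed when adjusted over the list alone (PHF8 family and partners, 7 members, limma with Benjamini-Hochberg adjusted p = 0.00197) and did not pass over all genes (limma with Benjamini-Hochberg adjusted p = 0.0643). In the same list E2F1, a transcription factor of the G1/S transition, rose from 42.6 ± 0.032 to 57.6 ± 1.46 TPM, adjusted over the list alone (limma with Benjamini-Hochberg adjusted p = 0.0328). The other 5 members did not pass, and the list did not pass camera (limma camera with Benjamini-Hochberg adjusted p = 0.751). The E2F1 call was lost without any 1 of the 4 libraries, without the trend and with the replicate block, whereas the PHF8 call was not.

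The series asks about transcription of the BCR-ABL1 fusion. BCR (ENSG00000186716) was at 39.8 ± 13.2 TPM in control and 35.9 ± 1.88 TPM in knockdown libraries, a log2 fold change of -0.10 ± 0.26 (SE) with a 95% confidence interval from -0.80 to 0.60 (limma with Benjamini-Hochberg adjusted p = 0.839). ABL1 (ENSG00000097007) was at 130.3 ± 11.5 and 127.7 ± 1.09 TPM, a log2 fold change of -0.03 ± 0.09 (SE) with a 95% confidence interval from -0.28 to 0.23 (limma with Benjamini-Hochberg adjusted p = 0.893). The intervals leave room for a BCR level from 0.573 to 1.51 times and an ABL1 level from 0.822 to 1.17 times that of the controls. Neither gene passed when adjusted over the list alone (BCR and ABL1 loci, 2 members, too few for camera). The TPM of either gene hold reads of the fusion and of the normal alleles, which the table does not separate. The BCR value turned to 0.23 without shControl replicate 1, and the ABL1 value to 0.063 without shControl replicate 2.

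**Figure D1:**
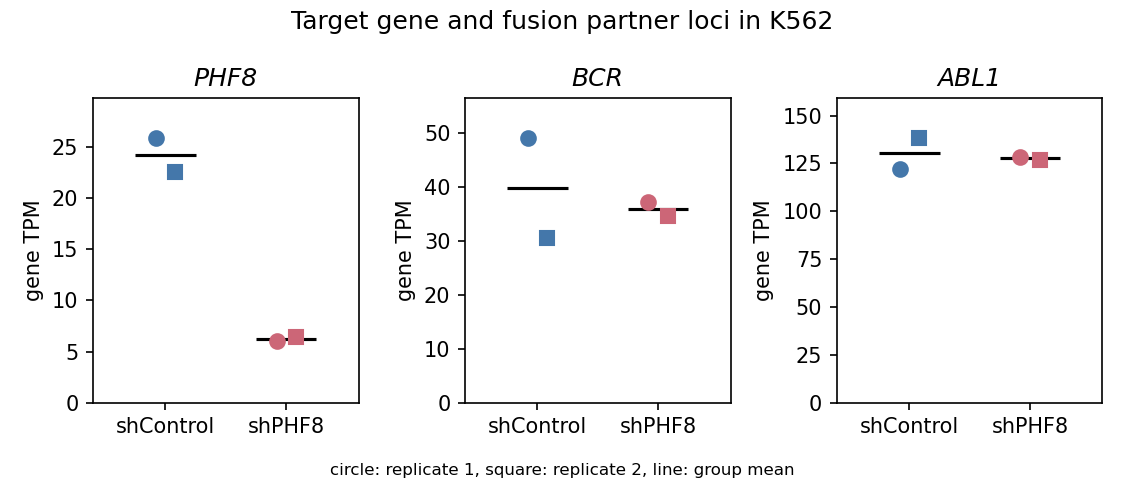
Gene TPM of PHF8, BCR and ABL1 in each library, with circles for replicate 1, squares for replicate 2 and a line at the mean of each group. The knockdown libraries lie at 6.06 and 6.42 TPM of PHF8, below both control libraries, while the BCR values of the knockdown libraries lie between those of the controls.

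Over all genes, none passed limma with Benjamini-Hochberg adjustment at 0.05, with 0 higher, 0 lower and a smallest adjusted p of 0.0554. At an unadjusted limma p under 0.05 there were 1086 genes with higher and 1328 with lower values in the knockdown libraries, where 549 would be expected by chance in both directions together. Both knockdown libraries lay on 1 side of both controls in 6066 genes, or 55.3%, against 33.3% by chance. The genes with the smallest p and a higher value, none of which passed, were EEF1A1, a translation elongation factor, from 4219 ± 161 to 8095 ± 18.5 TPM; HIST1H1C, a linker histone, from 1707 ± 58.7 to 3262 ± 101 TPM; REST, a transcriptional repressor of neuronal genes, from 4.91 ± 0.0438 to 35.9 ± 1.78 TPM; PDXDC1, from 32.5 ± 0.797 to 91.3 ± 3.40 TPM; and HBG2, a fetal globin, from 1683 ± 92.5 to 2958 ± 7.45 TPM. Those with a lower value were TPM4, a tropomyosin, from 193 ± 26.1 to 31.0 ± 1.69 TPM; SPCS1, a signal peptidase subunit, from 93.9 ± 8.04 to 21.9 ± 0.784 TPM; SRSF11, a splicing factor, from 205 ± 3.23 to 86.4 ± 0.871 TPM; and PSME3, a proteasome activator, from 220 ± 3.49 to 87.4 ± 4.49 TPM. NPIPA3 was at 13.9 and 13.3 TPM in the control libraries and listed at 0 in both knockdown libraries. All 10 had a limma Benjamini-Hochberg adjusted p of 0.0554. EEF1A1, PDXDC1, NPIPA3 and HBG2 have near-identical copies, so their values are uncertain. Under quantile normalization 17 genes were called higher and 20 lower by limma with Benjamini-Hochberg adjustment.

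Of the 30 gene lists tested, 9 passed limma's camera at the preset correlation, 5 upward and 4 downward, and 0 passed with an estimated correlation. The estimated correlation was 0.62 for granulocyte and monocyte markers, 0.40 for globins, 0.20 for ribosomal proteins and 0.15 for G1/S genes. It was below the preset 0.01 for the other lists that passed, such as -0.04 for histones. For those lists a higher correlation cannot explain the lost call. Camera with an estimated correlation uses the 2 residual degrees of freedom. Counts of members that rose or fell, here and below, are adjusted over the list alone, by Benjamini-Hochberg on limma's p; 0 members of any list passed over all genes. Over the lists together 147 of 720 memberships passed, which were 140 genes. Among all 10972 genes tested, 2414 had an unadjusted limma p under 0.05, a less strict threshold. The share outside the lists was not computed, so this total does not single out the listed genes. The number of memberships that passed was 93 without shControl replicate 1, 91 without shControl replicate 2, 55 without shPHF8 replicate 1, 62 without shPHF8 replicate 2, 84 without the trend and 88 with the replicate block. Libraries were left out 1 at a time, which leaves 1 sample in the group, and that sample is assumed to vary like the other group.

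**Figure D2:**
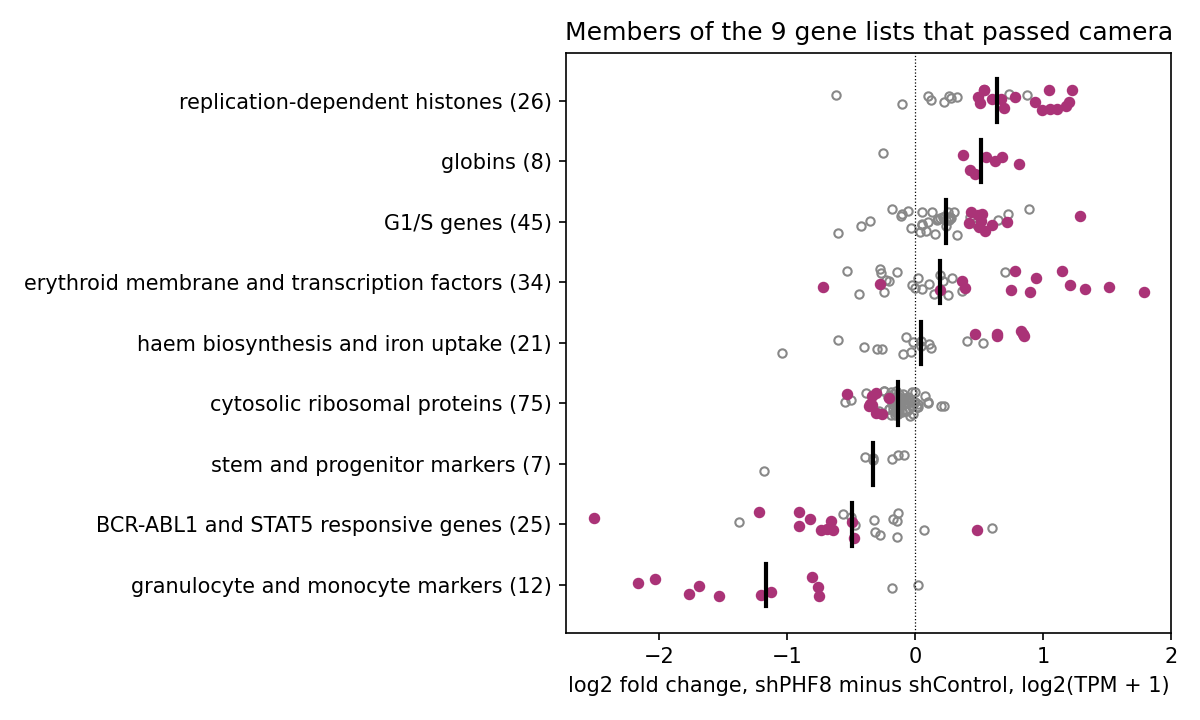
Log2 fold change, shPHF8 minus shControl, of each tested member of the 9 lists that passed camera, with the number tested in parentheses, filled points for members that passed when adjusted over the list alone and a vertical line at the median. Medians run from -1.17 for granulocyte and monocyte markers to 0.64 for replication-dependent histones.

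Most globins rose after PHF8 knockdown, as did a minority of the genes in 2 other erythroid lists. Of 8 globins tested, 7 rose and 0 fell: among them HBG2, HBG1 from 2915 ± 63.0 to 4679 ± 218 TPM, the embryonic HBE1 from 2504 ± 97.3 to 3368 ± 140 TPM, and HBA1 from 1717 ± 167 to 2646 ± 56.5 TPM. Only HBD, with a log2 fold change of -0.25 ± 0.38 (SE), did not pass. Of 21 genes of haem biosynthesis and iron uptake, 6 rose and 0 fell, including the transferrin receptor TFRC, from 299 ± 6.27 to 541 ± 11.1 TPM, and the haem enzymes CPOX, from 57.6 ± 2.29 to 103 ± 3.43 TPM, UROS, from 54.6 ± 0.958 to 99.1 ± 7.01 TPM, and FECH, from 77.8 ± 0.682 to 122 ± 0.322 TPM. Of 34 erythroid membrane and transcription factor genes, 12 rose and 2 fell. The spectrin SPTB rose by 0.95 ± 0.09 on the log2 scale, to 98.8 ± 2.56 TPM, and HEMGN rose by 0.75 ± 0.07, to 519 ± 10.9 TPM. The members that fell were GYPE, a glycophorin, from 199 ± 4.58 to 121 ± 0.728 TPM, and the glucose transporter SLC2A1, from 126 ± 0.982 to 103 ± 3.13 TPM.

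All 3 erythroid lists passed limma's camera upward with Benjamini-Hochberg adjusted p = 4.69e-06 for globins, 0.0364 for haem biosynthesis and iron uptake and 0.00591 for the membrane and transcription factor genes, with median log2 fold changes of 0.51, 0.05 and 0.20. For each of them the limma camera Benjamini-Hochberg adjusted p was 0.563 with an estimated correlation. Fry gave adjusted p of 0.0836, 0.0195 and 0.0200 (limma, Benjamini-Hochberg). Granulocyte and monocyte markers moved the other way in the same libraries, with a median of -1.17. Reads of HBG1 and HBG2, and of HBA1 and HBA2, can be exchanged, so the value of each single globin is uncertain. The haem list lost its camera call without shControl replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0914), shControl replicate 2 (0.0783) or shPHF8 replicate 2 (0.0561), and with the mean-TPM minimum of 5 (0.0558), quantile normalization (0.0887), no trend (0.0790) or the replicate block (0.0780); the membrane list's 12 risen members became 7 without shControl replicate 1, 6 without shPHF8 replicate 1, 7 without shPHF8 replicate 2, 7 without the trend and 8 with the replicate block, and its 2 fallen members became 1 without any 1 library, with a pseudocount of 0.1, median-of-ratios scaling or rescaled TPM, without the trend and with the replicate block. In the haem list 1 member fell without either shControl library, and its median ran from 0.03 with quantile normalization to 0.13 without shControl replicate 1.

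**Figure D3:**
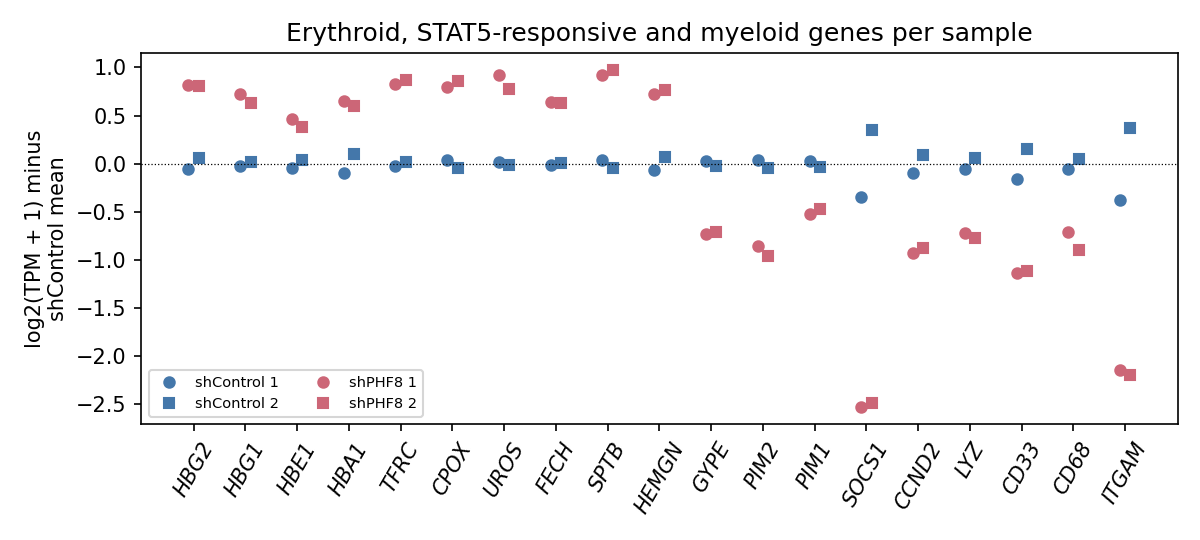
Per library, log2(TPM + 1) minus the mean of the control libraries for 19 genes, chosen by small p as named in the text for the 3 erythroid lists and the STAT5-responsive and granulocyte and monocyte lists, so members that did not pass are not shown. Both knockdown libraries lie above both controls for the erythroid genes HBG2 to HEMGN, and below both for GYPE, also erythroid, and for the 8 genes from PIM2 to ITGAM.

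Most of the granulocyte and monocyte markers tested fell in the knockdown libraries. Of 26 granulocyte and monocyte markers, 12 were tested, and of these 10 fell and 0 rose. Lysozyme (LYZ) fell from 71.9 ± 3.89 to 42.4 ± 1.13 TPM, the myeloid surface receptor CD33 from 31.1 ± 4.93 to 13.6 ± 0.187 TPM, the macrophage protein CD68 from 42.7 ± 2.15 to 24.0 ± 2.29 TPM, and the integrin ITGAM from 4.32 ± 1.91 to 0.145 ± 0.0274 TPM. The transcription factors CEBPB and CEBPD did not pass, with log2 fold changes of 0.02 and -0.18. The list passed camera downward (limma, Benjamini-Hochberg adjusted p = 6.07e-06) with a median of -1.17, and its adjusted p was 0.563 with an estimated correlation and 0.0745 by fry. With a mean-TPM minimum of 5 only 7 members were tested, 5 of them fell and the median was -0.76, since the members left out had few TPM and large falls on the log2 scale. Of 18 lymphocyte markers only 2 were tested, too few for camera: CD3D, part of the T-cell receptor complex, fell from 30.6 ± 1.34 to 12.9 ± 2.79 TPM. The CD3D call was lost without shControl replicate 2.

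Of 15 stromal and endothelial markers 4 were tested and 2 fell. Vimentin (VIM) fell from 492 ± 7.32 to 301 ± 2.86 TPM and the collagen COL1A2 from 10.5 ± 1.57 to 1.72 ± 0.0988 TPM, and the list did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.0841), though it did without shControl replicate 1 (0.0358). Stem and progenitor markers passed camera downward with a median of -0.33 (limma, Benjamini-Hochberg adjusted p = 0.0474), but 0 of 7 tested members passed when adjusted over the list alone. The transcription factors GATA2, MECOM and LYL1 had log2 fold changes of -0.39, -0.33 and -0.13, and the receptor KIT was at 2.66 ± 0.796 and 0.781 ± 1.11 TPM. This list's adjusted p was 0.563 with an estimated correlation and 0.0542 by fry. The camera call ended without shControl replicate 1 (0.0851), shControl replicate 2 (0.0787), shPHF8 replicate 1 (0.0896) or shPHF8 replicate 2 (0.0734), and with a pseudocount of 0.1 (0.0520), a mean-TPM minimum of 5 (0.0731), no trend (0.0682) or the replicate block (0.0751), and the median was -0.18 without shPHF8 replicate 1. Megakaryocyte markers went both ways: 3 of 12 tested members rose and 2 fell. The platelet tubulin TUBB1 rose from 12.1 ± 1.55 to 35.1 ± 0.343 TPM, CD36 from 14.1 ± 0.624 to 25.8 ± 1.2 TPM and LTBP1 from 22.7 ± 5.48 to 40.4 ± 2.12 TPM, while PLEK and RUNX1 fell by 2.12 and 0.53 on the log2 scale. The list did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.693), whose direction was upward where the median was -0.07 and the mean -0.04, and 0 of its members passed without either shPHF8 library. Without the trend 2 rose and 1 fell, and with the mean-TPM minimum of 5 only RUNX1 fell.

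Part of the genes responsive to BCR-ABL1 and STAT5 signalling fell in the knockdown libraries. Of 25 tested, 11 fell, 1 rose and 13 did not pass. In the same libraries 10 of 12 granulocyte and monocyte markers fell and 7 of 8 globins rose, so a change within cells is not separated here from a change in the mix of cells. The serine kinases PIM2 and PIM1, known STAT5 targets, fell from 252 ± 10.7 to 133 ± 6.84 TPM and from 787 ± 25.3 to 558 ± 15.5 TPM. The cytokine signalling inhibitor SOCS1 fell from 22.8 ± 7.97 to 3.06 ± 0.0934 TPM and cyclin D2 (CCND2) from 90.8 ± 8.24 to 47.9 ± 1.21 TPM. The member that rose was EGR1, an immediate early transcription factor, from 292 ± 20.3 to 409 ± 6.27 TPM. The list passed camera downward with a median of -0.50 (limma, Benjamini-Hochberg adjusted p = 1.00e-05); the adjusted p was 0.508 with an estimated correlation, from an unadjusted 0.0339, and 0.0189 by fry. The number of fallen members was 4 without shControl replicate 1, 5 without shControl replicate 2, 5 without shPHF8 replicate 1, 7 without shPHF8 replicate 2 and 7 with the replicate block, with PIM2, PIM1, SOCS1 and CCND2 among them each time, and the rise of EGR1 in this list was lost without either shPHF8 library.

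Of 36 JAK-STAT, PI3K and RAS signalling components, 3 rose and 1 fell. The kinase subunit PIK3CA rose from 21.4 ± 1.88 to 40.7 ± 1.90 TPM, STAT3 from 93.1 ± 9.88 to 145 ± 4.59 TPM and NRAS from 123 ± 10.9 to 176 ± 0.165 TPM, while STAT5B fell from 191 ± 18.4 to 121 ± 2.86 TPM. Of 14 BCL2 family genes tested, 1 fell: BCL2L1, which encodes the survival protein BCL-xL and is known to respond to STAT5, from 226 ± 1.25 to 144 ± 17.7 TPM; BAX was at 66.9 ± 3.74 and 52.5 ± 2.50 TPM. Of 15 immediate early genes 4 rose, namely EGR1, KLF10, JUN and DUSP1, and 2 fell, namely ATF3 and IER2. Of 12 NF-kB responsive genes 3 fell, namely NFKB2, from 33.5 ± 0.875 to 15.5 ± 1.16 TPM, TNFAIP3 and CCL2. None of these 4 lists passed camera (limma, Benjamini-Hochberg adjusted p = 0.156 for the signalling components, 0.337 for the BCL2 family, 0.339 for immediate early genes and 0.156 for NF-kB responsive genes), and for the BCL2 family the mean was 0.08 where the median was -0.14 and the test downward. The 4 signalling calls were lost without any 1 library, without the trend and with the replicate block, and became 6 higher and 1 lower with the mean-TPM minimum of 5 or median-of-ratios scaling. Also lost were the 6 immediate early calls without either shPHF8 library and the 3 NF-kB calls without either shControl library; with the replicate block only NFKB2 passed, and NFKB1 joined as higher without the trend and under the 3 other scalings. Of the immediate early genes 1 passed higher and 1 lower without shControl replicate 1, and 4 higher and 1 lower without shControl replicate 2; the BCL2L1 call in its family was lost without any library but shPHF8 replicate 1, without the trend, and with median-of-ratios scaling, quantile normalization or the replicate block, and another member passed as higher without shControl replicate 2.

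Most replication-dependent histone genes, and a minority of the genes of the G1/S transition, rose in the knockdown libraries. In the same libraries 10 of 12 granulocyte and monocyte markers fell and 7 of 8 globins rose. A change within cells is thus not separated from a change in the mix of cells here either. Of 26 histone genes, 16 rose and 0 fell: HIST1H1C, HIST2H2AA3 from 140 ± 12.2 to 323 ± 0.604 TPM, HIST1H2BK from 1535 ± 11.4 to 2332 ± 86.1 TPM and HIST2H2BE from 84.1 ± 6.91 to 192 ± 17.7 TPM. Of 45 G1/S genes, 10 rose and 0 fell. The replicative helicase subunits MCM6 and MCM7 rose from 103 ± 17.5 to 251 ± 7.66 TPM and from 262 ± 7.89 to 371 ± 15.8 TPM, and the ribonucleotide reductase subunit RRM2 from 107 ± 1.75 to 152 ± 10.7 TPM. Both lists passed camera upward (limma, Benjamini-Hochberg adjusted p = 9.72e-11 for histones and 4.69e-06 for G1/S genes), with medians of 0.64 and 0.24. The adjusted p was 0.482 with an estimated correlation for histones, from an unadjusted 0.0161, and 0.563 for G1/S genes, and fry gave 0.0119 and 0.0917. Histone genes share near-identical sequence, so the value of each is uncertain. The 16 risen histone genes became 10 without shPHF8 replicate 1. The 10 risen G1/S genes became 9, with 1 gene fallen, without shControl replicate 1, 1 without shControl replicate 2 and 0 without shPHF8 replicate 1, without shPHF8 replicate 2, with the replicate block or without the trend.

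Of 50 G2/M genes, 2 fell and 0 rose, namely CKS2, from 253 ± 16.8 to 154 ± 3.64 TPM, and CDCA8, from 139 ± 7.05 to 92.2 ± 0.552 TPM, although 35 of the 50 had values above 0 and the median was 0.12. The list did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.0993), but passed upward without shControl replicate 1 (0.00188). Of 19 CDK inhibitors and p53-pathway genes, the cell cycle inhibitor CDKN1A rose from 18.7 ± 1.44 to 31.4 ± 0.855 TPM and TP53INP1 fell from 13.0 ± 1.2 to 5.62 ± 0.329 TPM (limma camera, Benjamini-Hochberg adjusted p = 0.949). Of 30 MYC target genes, TFRC and MTHFD2 rose and CCND2 and LDHA fell (limma camera, Benjamini-Hochberg adjusted p = 0.693). The 2 G2/M calls were lost without shControl replicate 2 or either shPHF8 library and became 4 higher and 3 lower without shControl replicate 1. They were also lost without the trend and with the replicate block, and the CDKN1A and TP53INP1 calls without any 1 library and with the replicate block. The MYC list held 3 higher and 2 lower members without either control library, 1 higher without shPHF8 replicate 1, 0 without shPHF8 replicate 2, and 1 higher and 1 lower without the trend or with the replicate block.

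Most cytosolic ribosomal protein genes had slightly lower values in the knockdown libraries, and few fell by the test. Of 75 genes, 64 had values below 0, 9 fell and 0 rose. RPL9 fell from 2438 ± 29.3 to 1928 ± 56.9 TPM, RPL35A from 1453 ± 25.6 to 1147 ± 23.9 TPM, RPL36 from 1574 ± 42.8 to 1272 ± 13.5 TPM and RPL24 from 1656 ± 5.35 to 1385 ± 12.4 TPM. The share of all TPM in these genes was 13.0% and 13.3% in the control libraries and 12.4% and 11.9% in the knockdown libraries. The list passed camera downward with a median of -0.13 (limma, Benjamini-Hochberg adjusted p = 7.38e-08), and its adjusted p was 0.563 with an estimated correlation and 0.0917 by fry. The 9 calls became 0 without any 1 library, and also with median-of-ratios scaling, with TPM rescaled without the mitochondrial and 20 most abundant genes, without the trend and with the replicate block. RNA polymerase I and rRNA processing genes had 0 members that passed out of 34 (limma camera, Benjamini-Hochberg adjusted p = 0.751); TAF1C was at 24.2 ± 1.24 and 9.78 ± 3.77 TPM and NIP7 at 67.0 ± 19.5 and 114 ± 12.2 TPM.

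Lists of other enzymes that act on the histone marks of PHF8 did not pass camera. Of 10 H3K9 and H4K20 methyltransferases, PRDM2 fell from 34.0 ± 2.67 to 12.6 ± 0.31 TPM, and KMT5B did not pass, at 23.9 ± 2.62 and 35.4 ± 6.16 TPM (limma camera, Benjamini-Hochberg adjusted p = 0.693). Fry, which does not compare a list with the other genes, gave this list downward (limma, Benjamini-Hochberg adjusted p = 0.0195). Of 9 other H3K9 demethylases 0 passed; KDM4A was at 77.4 ± 5.44 and 61.0 ± 1.55 TPM and JMJD1C at 53.7 ± 0.801 and 67.0 ± 4.11 TPM (limma camera, Benjamini-Hochberg adjusted p = 0.499). In the methyltransferase list 1 higher member joined without shControl replicate 2 and the lower members became 2 without shPHF8 replicate 2.

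Metabolic and stress lists went both ways. Of 31 genes of the amino acid and unfolded protein responses, 7 rose and 6 fell: the endoplasmic reticulum chaperone HSPA5 rose from 495 ± 1.5 to 734 ± 55.1 TPM and EDEM1 fell from 46.6 ± 3.42 to 23.2 ± 1.26 TPM. Of 30 glycolysis and hypoxia-responsive genes, the phosphofructokinase PFKL rose from 18.6 ± 0.682 to 57.2 ± 11.3 TPM, and the pyruvate kinase PKM fell from 215 ± 5.30 to 147 ± 7.57 TPM, as did EGLN3 and LDHA. Of 13 mitochondrially encoded genes, MT-ND6 fell from 4858 ± 15.0 to 3702 ± 13.5 TPM and MT-ATP8 from 20955 ± 381 to 19168 ± 203 TPM, while MT-CYB and MT-CO3 rose by 0.13 and 0.12 on the log2 scale. None of 49 nuclear oxidative phosphorylation genes passed, with NDUFA5 at 369 ± 25.4 and 467 ± 18.9 TPM, and none of 25 cholesterol biosynthesis genes did, with ACAT2 at 103 ± 4.14 and 127 ± 0.0729 TPM. None of these 5 lists passed camera (limma, Benjamini-Hochberg adjusted p = 0.693 for the stress, glycolysis and cholesterol lists, 0.949 for mitochondrially encoded and 0.716 for nuclear oxidative phosphorylation genes). For cholesterol biosynthesis the mean was -0.00817 where the median was 0.03 and the test upward, and for mitochondrially encoded genes the median was 0.00133 where the mean was -0.02 and the test downward. The 13 stress-response calls became 4 higher and 4 lower without shControl replicate 2 and 0 without any other library or without the trend. The 4 glycolysis calls became 0 without shControl replicate 1 or shPHF8 replicate 1, 1 higher and 1 lower without shControl replicate 2, 1 higher without shPHF8 replicate 2 or without the trend and 0 with the replicate block. Of the 4 mitochondrial calls only that of MT-ND6 was kept without any 1 library, without the expression filter and with the replicate block; 0 were kept without the trend, and quantile normalization gave 3 higher and 6 lower.

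Antigen presentation and cytoskeletal genes held members that changed, and neither list passed camera. Of 8 antigen presentation genes tested, HLA-E fell from 57.0 ± 3.75 to 30.9 ± 0.779 TPM and the peptide transporter TAP1 from 7.54 ± 0.151 to 3.91 ± 0.111 TPM (limma camera, Benjamini-Hochberg adjusted p = 0.156). Of 21 interferon-stimulated genes 0 passed, with IFITM3 at 225 ± 3.90 and 170 ± 15.1 TPM; camera gave an adjusted p of 0.949 with an upward direction and fry a downward one (limma, Benjamini-Hochberg). Of 34 cytoskeleton and adhesion genes, 3 rose and 4 fell: the GTPase RAC1 rose from 172 ± 6.60 to 338 ± 15.3 TPM, as did ITGB1 and ANXA2, and TPM4 fell, as did VIM, LGALS1 and ZYX (limma camera, Benjamini-Hochberg adjusted p = 0.693). The 2 antigen presentation calls became 1 without shControl replicate 1 and 0 without either shPHF8 library, and only HLA-E passed with a pseudocount of 0.1 or 0.5, the 3 other scalings, robust moderation or the replicate block. The 3 risen cytoskeletal genes became 1 without shPHF8 replicate 1 and 2 without shPHF8 replicate 2, and without the trend 1 rose and 2 fell. For PHF8 family and partners the median was 0.00673 where the mean was -0.22 and the test downward.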

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

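The threshold of 0.1 and the fit on genes with 1 listed transcript were chosen after seeing the data; the other alternatives were fixed before. Limma with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower under every alternative fixed before except quantile normalization, with 17 higher and 20 lower; leaving out each library gave a range of 0 to 0, with 1495 to 2210 genes at an unadjusted p under 0.05. A threshold of 0.1 gave 191 higher and 236 lower, and genes with 1 listed transcript gave 54 higher and 73 lower. PHF8 kept its direction under all of these that hold it, with limma Benjamini-Hochberg adjusted p from 0.0597 to 0.275. Without each library the BCR value ranged from -0.44 to 0.23 and turned to 0.23 without shControl replicate 1; the ABL1 value ranged from -0.12 to 0.063 and turned to 0.063 without shControl replicate 2; the cause was not tested, though each of these fits has fewer samples. All 9 lists that passed camera kept their direction under all 14 alternatives fixed before, and 7 of them their call at the preset correlation; 0 of the 9 passed with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p from 0.482 to 0.563).

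The camera call of stem and progenitor markers ended with a pseudocount of 0.1 (0.0520), a mean of at least 5 TPM (0.0731, 6 genes tested in place of 7), no trend (0.0682) and without each library (0.0734 to 0.0896). That of haem biosynthesis and iron uptake ended with a mean of at least 5 TPM (0.0558), quantile normalization (0.0887) and no trend (0.0790), and ranged from 0.0398 to 0.0914 without each library. Leaving out a library means fewer samples; for the other settings the cause was not tested. Among single named genes, 1151 values stayed on their side of the threshold with their direction and 18 passed under quantile normalization. Among the other lists 290 values stayed on their side of the threshold, where direction was not compared. The other 2 passed, G2/M genes and stromal and endothelial markers without shControl replicate 1. Directions could turn: the median of other H3K9 demethylases was 0.14, and -0.02 without shPHF8 replicate 2. Since the depth is unknown, it cannot be said what depth limits.

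Replicate numbers are shared by the groups in the labels. Over genes, deviations of same-numbered libraries from their group means correlated at -0.0289, so no pairing was seen over the genes as a whole. This value cannot show whether same-numbered libraries were prepared together. With the replicate number as a block, limma called 0 genes higher and 0 lower with 1949 at an unadjusted p under 0.05, and 2 lists lost their camera call, haem biosynthesis and iron uptake (0.0780) and stem and progenitor markers (0.0751).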

Other observations

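The fit on genes with 1 listed transcript, the S100A9 test, the MT-ND6 test and the tests of list medians under other scalings were chosen only after the results they bear on were seen, and the genes named in the first 2 paragraphs after their values were seen.

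Among the 3233 tested genes with 1 listed transcript, whose values do not depend on how reads are divided between listed isoforms, limma with Benjamini-Hochberg adjustment over these genes alone called 73 lower and 54 higher in the knockdown libraries. Genes that fell included TCN1, a vitamin B12 carrier of neutrophil granules, from 23.3 ± 2.43 to 2.86 ± 0.596 TPM (adjusted p = 0.0221), the tetraspanin CD53 from 112 ± 17.9 to 47.8 ± 1.94 TPM (0.0331) and the lysosomal protein LAPTM5 from 83.1 ± 8.21 to 38.5 ± 2.96 TPM (0.0287). CLC, the eosinophil and basophil Charcot-Leyden crystal protein, was at 6.36 and 5.99 TPM in the control libraries and PRF1, perforin, at 4.27 and 6.79 TPM; both were listed at 0 in both knockdown libraries. PIM1 (0.0287), SOCS1 (0.0336), STAT5B (0.0425), CCND2 (0.0287) and cyclin D1, CCND1 (0.0487), also fell. So did ALDH1A1, a retinaldehyde dehydrogenase, from 30.8 ± 1.71 to 11.4 ± 1.79 TPM (0.0308). HES1, a NOTCH-responsive repressor, fell from 54.3 ± 2.79 to 26.7 ± 1.27 TPM (0.0243). EGR1, a BCR-ABL1 and STAT5 responsive gene like PIM1, SOCS1 and CCND2, rose in this fit (0.0435). Their list, with 11 members there, did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.0652).

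Genes that rose in the same fit included the erythroid transcription factor KLF1, from 141 ± 2.67 to 186 ± 3.39 TPM (limma with Benjamini-Hochberg adjusted p = 0.0413), catalase, CAT, from 151 ± 3.16 to 236 ± 3.71 TPM (0.0221), the haem enzyme CPOX (0.0232), the helicase subunit MCM6 (0.0287) and LBH, from 4.99 ± 0.0549 to 23.8 ± 0.965 TPM (0.0221). Replication-dependent histones was the only list of the 26 tested there to pass camera at the preset correlation (adjusted p = 6.03e-09). The granulocyte and monocyte markers, with 6 members there, did not (0.118). Nor did the erythroid membrane and transcription factor genes, with 6 members and a median of 0.09 (0.390). Haem biosynthesis and iron uptake, with 4 members, did not pass either (0.390). An estimated correlation was not tried there. In the fit on all genes it gave the histones a camera adjusted p of 0.482. The calls come partly from the separate fit: with the p-values of the fit on all 10972 genes, 30 genes with 1 transcript and 21 of the 7739 with more would pass when adjusted apart. The median residual SD was 0.152 on the log2 scale for genes with 1 transcript and 0.156 for the others, and it was lower in 10 of 10 bins of equal gene number by expression. This fit was not repeated without each library.

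Of 12 granulocyte and monocyte markers tested, 10 fell, adjusted over the list alone (limma, Benjamini-Hochberg). The fall held under each scaling tried. The list's median log2 fold change was -1.15, -1.09 and -1.23 under the 3 other scalings, against -1.17. The median of all tested genes was -0.02, and -0.0039, 0.0042 and -0.008 under those scalings. They thus shifted genes little as a whole and could hardly have removed the fall. Such scalings cannot show a change in total RNA per cell, which was not tested. Monocytes or neutrophils mixed into the control cultures would bring S100A9, among their most abundant transcripts; its fall was 5.49% of the fall of LYZ in TPM, 1.62 against 29.5 TPM. Mixed cells as the cause predicted a fall of S100A9 at least as large as that of LYZ. The upper limit of the ratio, at 2 standard errors of each fall, was 10.1%. It lay below that prediction, but just above the 10% set as the bound against mixed cells. The test rests on a single gene with a small fall, so mixed cells stay open. The PHF8 knockdown itself, in which the K562 cells may express fewer myeloid genes, also stays open and was not tested apart from the hairpin or the culture.

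The most abundant BCR transcripts were exchanged between the groups while the sum was similar. BCR-001 was at 46.9 and 23.7 TPM in control and 9.52 and 11 TPM in knockdown libraries, and BCR-002 was listed at 0 in both control libraries and at 22 and 20.5 TPM in the knockdown libraries. Transcripts listed at 0 in both libraries of one side and at 20 TPM or more in both of the other numbered 31 in the real split, against 21 and 25 in the other 2 splits of the 4 libraries, and such exchanges between single libraries numbered 216 within the control and 233 within the knockdown group. The BCR exchange is thus consistent with random assignment of reads to isoforms in each library. A change of BCR isoforms by the knockdown stays possible and was not tested.

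Of 26 replication-dependent histone genes 16 rose, adjusted over the list alone (limma, Benjamini-Hochberg). The list's median log2 fold change was 0.65, 0.68 and 0.65 under the 3 other scalings, against 0.64. The rise thus held under each scaling tried. These scalings shifted genes little as a whole, so they could hardly have removed it. A change in total RNA per cell was not tested. Less complete selection of polyadenylated RNA in the knockdown libraries could raise these transcripts, most of which end without a poly(A) tail, and would then be likely to raise MT-ND6, whose transcript has a short tail or none. MT-ND6 had a log2 fold change of -0.39 in place of a rise. The strandedness of the libraries is not given, so its reads may include those of the genes on the opposite strand, a point weighed after the value was seen, and this explanation stays open. A change in the share of cells in S phase after PHF8 knockdown is another open explanation and was not tested.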
